A study of Homo sapiens with 12 samples.

How the data were processed

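Human bone marrow CD34+ stem and progenitor cells with a lentiviral RUNX3 knock-down or an empty vector were harvested undifferentiated or after 24 h in erythroid medium, with 3 biological replicates in each of 4 groups per the labels. The 12 RNA libraries were strand-specific, paired-end and reduced in ribosomal RNA per the series' design text. The authors deposited one table of FPKM values per library, which are fragments per kilobase of transcript scaled to the mapped fragments of the library, with 1 row per RefSeq transcript. Per the submitters' processing notes the tools were Trimmomatic, HISAT2, featureCounts, Cufflinks, Cuffdiff and DESeq2 in Galaxy, with the genome build hg19 (GRCh37). Tool versions and settings are not given in the sources used here. The FPKM columns and their lower and upper bounds are values of Cufflinks per the file headers, with no scaling between libraries stated.

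The authors also deposited 4 tables that compare the groups. Per the file headers these hold a mean normalized count, which is a signal averaged over the 6 libraries of a comparison, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value for each of 65022 rows. The deposited log2 fold changes fall short of the raw ratios in size, so the authors may have shrunk them. Sheets with only the rows past the threshold repeat part of these tables and were not used here.

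Each library's table held 68845 rows, of which 40160 carried a gene symbol in the file and 67835 matched the RefSeq gene table of GRCh38.p14, which served for names only, so that 622 were named by neither. Coordinates are those of the files on hg19. Rows of one gene were summed, which gave 27952 genes, 12333 of them from several rows. For 17 genes the Cufflinks status was other than OK in at least 1 library. Among the genes tested, 14 have a symbol stored as a date in the files, and none of these is named. XIST, TSIX and genes on chromosome Y were left out.

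The depth of each library was estimated from transcripts of at least 1000 bases and 10 FPKM that are the only one of their gene, as the median number of fragments that the distance between the FPKM and its upper bound implies. It ranged from 23370000 to 32690000 fragments. Within groups, libraries correlated across genes at a Pearson correlation between 0.943 and 0.974.

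Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 11769 in all. Values were analysed as log2(FPKM + 1), so a fold change given here is on that scale and understates the change of genes with low values. One linear model of the 4 group means was fitted over all 12 libraries with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and a trend of the variance with the mean. Tests were moderated and two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The comparisons were knock-down against empty vector in each culture, erythroid against CD34+ cells with each construct, and the difference between the knock-down effects of the cultures (interaction). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

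The gene lists, the design, the naming rule and the alternatives were fixed before the data were examined. There were 29 lists: erythroid transcription factors, globins, red cell membrane, haem and iron, stem and progenitor, granulocyte, monocyte, dendritic, megakaryocyte, mast cell, lymphoid, stromal, RUNX family, MHC class II, ribosomal proteins, ribosome biogenesis, S phase, G2 and mitosis, p53, stress response, interferon, NF-kB, immediate early, transforming growth factor beta, glycolysis, cholesterol and fatty acid, lysosome, histones and mitochondrially encoded genes. The 28 with at least 5 tested members were tested with camera of limma, two-sided, with a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over the lists of a comparison. Genes were named by a rule: RUNX3, RUNX1, RUNX2 and CBFB, and GATA1, KLF1, HBB, HBA1, CD34, KIT, SPI1, CEBPA and MPO in every comparison. To these came the 6 genes that rose most and the 6 that fell most past the threshold with at least 5 FPKM in the higher group, a locus of at least 1000 bases and no overlap between the groups' libraries, of which chance leaves 10% without overlap at 3 against 3. From each list came up to 3 rising and 3 falling members with the smallest adjusted p, or the 2 most abundant where none passed. The text uses fewer than the rule gives, and some genes it gives are not reported here. For the interaction no gene met the same limits, and the 2 that passed were named after their values were seen. A gene listed at exactly 0 in a group may be a failed estimate, so its values are given per library.

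Replicate numbers recur in all groups. The labels do not say what a number marks, so pairing was checked in the data before calls were compared. Deviations from the group means correlated at 0.125 to 0.501 in the 18 pairs of libraries with the same number (median 0.308) and at −0.426 to 0.16 in the 36 pairs with other numbers (median −0.179). The numbers therefore pair the samples by the data, and a fit with the number as a block is given where it changes a call or moves a count by more than 1.5 times. Counts with the block are of members that passed over all genes, and p values are without the block unless it is named beside them.

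The pipeline was tested on simulated data with 50 genes changed at each of 4 sizes among the 11769. For knock-down in erythroid medium it called 36% of genes changed by 0.5 log2 units, 82% at 1 and 94% at 1.5 and at 2, with 7 false calls. For knock-down in CD34+ cells the shares were 44%, 84%, 98% and 94%, with 6 false calls. For the effect of the medium with the empty vector they were 46%, 86%, 94% and 94%, with 6 false calls, and under knock-down 54%, 88%, 88% and 96%, with 18 false calls.

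The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, loci under 300 bases left out with rescaling, the replicate block with and without that scaling, the row with the highest mean in place of the sum, genes with a status other than OK left out, no variance trend, a fit of only the 2 groups compared, an estimated correlation in the list tests, and each library left out in turn. Other splits of the libraries were run as well. Words of 7 bases in 3' untranslated regions were taken from GENCODE v29 transcripts of GRCh38, as sequence only.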

Results

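RNA was sequenced from human bone marrow CD34+ haematopoietic stem and progenitor cells carrying a lentiviral construct that knocks down RUNX3, or an empty vector. RUNX3 is a transcription factor of the RUNX family, which binds DNA together with CBFB. After selection, cells were harvested undifferentiated from expansion culture or after 24 h in erythroid medium. This made 4 groups of 3 biological replicates and 12 libraries. The values are FPKM as deposited by the authors, with genes placed on hg19. The files give no read totals, so depth was estimated from the bounds of each FPKM. In fragments it came to 27010000, 32690000 and 26330000 for replicates 1 to 3 of the CD34+ empty vector group and to 28100000, 25410000 and 24730000 for the CD34+ knock-down group. The erythroid empty vector libraries came to 31730000, 23370000 and 27400000, and the erythroid knock-down libraries to 30850000, 28500000 and 28950000. Between 11188 and 11361 genes reached 1 FPKM in a library. Loci shorter than 300 bases took between 19.6% and 44.1% of the FPKM total of a library, with the highest share in CD34+ empty vector replicate 2.

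The targeted gene was examined first, in every library. RUNX3 (chromosome 1, 25226002 to 25291501) stood at 5.31, 7.98 and 4.29 FPKM in the 3 CD34+ empty vector libraries and at 2.69, 2.13 and 2.38 FPKM in the 3 CD34+ knock-down libraries. After erythroid medium it stood at 3.44, 3.35 and 3.51 FPKM with the empty vector and at 2.12, 2.19 and 2.49 FPKM under knock-down. In both cultures each knock-down library lay below every empty vector library. In CD34+ cells RUNX3 fell from 5.86 ± 1.91 to 2.40 ± 0.281 FPKM (mean ± SD, n = 3), a log2 fold change of −0.98 ± 0.16 (SE) with an adjusted p of 0.0265. In erythroid medium it was 3.43 ± 0.0829 FPKM with the empty vector and 2.26 ± 0.197 FPKM under knock-down, a log2 fold change of −0.44 ± 0.16 with an adjusted p of 0.104, which does not pass the threshold, and 0.0693 with the replicate number as a block. Over the alternative settings the adjusted p ranged from 0.0134 to 0.25 in CD34+ cells and from 0.0147 to 0.418 in erythroid medium. Between the cultures RUNX3 differed by a log2 fold change of −0.59 with the empty vector (adjusted p 0.0749, and 0.0422 with the block) and of −0.06 under knock-down (adjusted p 0.94). The RUNX3 locus also holds the microRNA gene MIR6731.

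**Figure D1:**
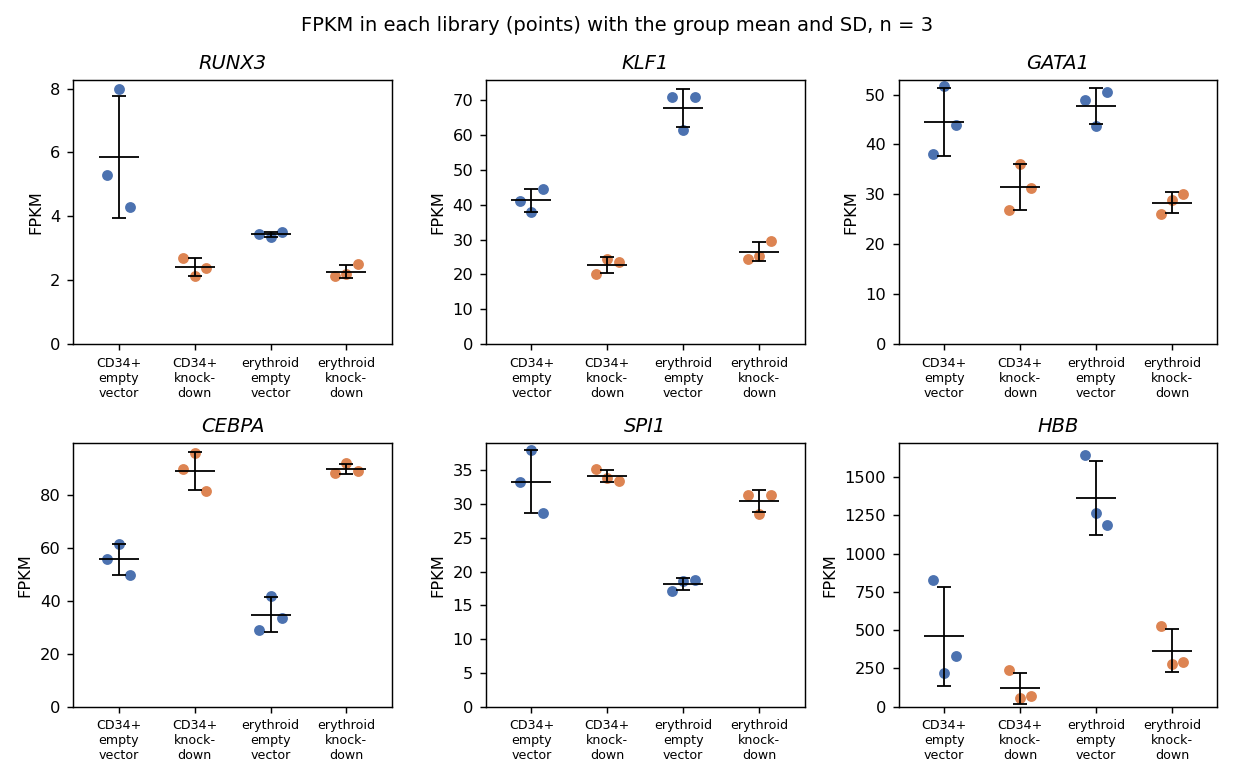
FPKM (vertical axis) of RUNX3, KLF1, GATA1, CEBPA, SPI1 and HBB in each of the 12 libraries by group, with the group mean and SD as bars (n = 3). KLF1 averaged 67.8 FPKM in erythroid empty vector libraries and 26.5 FPKM in erythroid knock-down libraries.

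The comparison of knock-down with empty vector after 24 h in erythroid medium asks which transcripts changed with the construct while red cell genes are being induced. It does not set an effect of RUNX3 apart from other effects of the construct, and RUNX3 itself did not pass here. Members of the red cell membrane, globin, haem and platelet lists fell, 17 of 20, 9 of 10, 14 of 22 and 14 of 22 of them, and 5 of 20 members of the granulocyte list rose. With an estimated correlation the red cell membrane and granulocyte lists pass (adjusted p = 0.0224 for both) and the others do not, as given below. KLF1, the transcription factor that activates adult beta-globin (chromosome 19, 12995236 to 12998017), fell from 67.8 ± 5.48 to 26.5 ± 2.76 FPKM (SD, n = 3). GATA1, the main erythroid GATA factor (chromosome X, 48644982 to 48652717), fell from 47.7 ± 3.56 to 28.3 ± 2.10 FPKM. CEBPA, a transcription factor of granulocyte commitment (chromosome 19, 33790840 to 33793470), rose from 34.8 ± 6.50 to 89.7 ± 1.92 FPKM.

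Among the red cell membrane and skeleton genes, 17 of 20 tested members fell and 0 rose, and 19 fell when adjusted over the list alone. The median log2 fold change was −1.35, with an adjusted p of 1.82e-16 in the list test. It was the list with the lowest adjusted p. The Kell antigen gene KEL fell from 6.05 ± 0.539 to 2.15 ± 0.154 FPKM, the skeletal protein 4.1 gene EPB41 from 52.4 ± 2.44 to 33.1 ± 0.580 FPKM, and EPB42 from 3.24 ± 0.802 to 0.508 ± 0.206 FPKM. With an estimated correlation the adjusted p of this list was 0.0224, and with both the estimate and the replicate block it was 0.163.

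The globins and their chaperone gave 9 of 10 members that fell and 0 that rose, with all 10 past the threshold when adjusted over the list alone. Their median log2 fold change was −2.48 and the adjusted p of the list was 2.33e-08 (adjusted p = 0.12 with an estimated correlation). The embryonic globin gene HBE1 (chromosome 11, 5289580 to 5291373) fell from 21.3 ± 7.02 to 2.02 ± 0.509 FPKM, and the beta-globin pseudogene HBBP1 (chromosome 11, 5263185 to 5264822) from 66.3 ± 41.6 to 7.52 ± 6.88 FPKM. The fetal globin gene HBG1 (chromosome 11, 5269502 to 5271087) fell from 135 ± 28.5 to 19.7 ± 7.57 FPKM and HBA1 (chromosome 16, 226650 to 227521) from 407 ± 193 to 62.3 ± 26.1 FPKM. Reads of HBG1 and HBG2, and of HBA1 and HBA2, are hard to tell apart, so these values are uncertain. HBB, the adult beta-globin (chromosome 11, 5246696 to 5248301), was 1360 ± 244 FPKM with the empty vector and 367 ± 141 FPKM under knock-down. Its adjusted p was 0.0544, and 0.00201 with the replicate block.

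Of 22 haem synthesis and iron uptake genes, 14 fell and 0 rose, and 16 fell when adjusted over the list alone. The median log2 fold change was −0.62 and the list's adjusted p was 2.95e-07 (adjusted p = 0.0592 with an estimated correlation). The mitochondrial porphyrin transporter gene ABCB6 fell from 12.1 ± 0.715 to 5.32 ± 0.497 FPKM, PPOX, which makes protoporphyrin, from 12.9 ± 1.76 to 6.58 ± 0.513 FPKM, and BLVRB, a biliverdin reductase, from 189 ± 8.96 to 80.4 ± 11.8 FPKM. Among the erythroid transcription factors and the erythropoietin receptor, 8 of 17 fell and 1 rose, both over all genes and adjusted over the list alone. The median was −0.19 and the adjusted p 0.00265 (adjusted p = 0.402 with an estimated correlation). GFI1B, a repressor needed in red cell and platelet precursors (chromosome 9, 135854098 to 135867084), fell from 39.8 ± 4.75 to 18.1 ± 0.686 FPKM. TAL1, a partner of GATA1 (chromosome 1, 47681962 to 47698007), fell from 65.2 ± 3.09 to 41.4 ± 3.89 FPKM. The member that rose was MYB, a factor of dividing progenitors (chromosome 6, 135502453 to 135540311), from 108 ± 4.51 to 145 ± 5.19 FPKM.

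The megakaryocyte and platelet list had 14 of 22 members that fell and 0 that rose, 19 falling when adjusted over the list alone. Its median was −1.23 and its adjusted p 1.24e-09 (adjusted p = 0.225 with an estimated correlation). The platelet chemokine genes led it. PPBP (chromosome 4, 74852156 to 74853907) fell from 119 ± 12.8 to 11.2 ± 6.28 FPKM, a log2 fold change of −3.42 ± 0.34 (SE) with an adjusted p of 0.000555. PF4 (chromosome 4, 74846542 to 74847841) fell from 79.7 ± 14.4 to 13.8 ± 3.6 FPKM, and the platelet receptor gene CLEC1B from 4.79 ± 1.34 to 0.459 ± 0.0797 FPKM.

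In the granulocyte list 5 of 20 members rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. With the replicate block 16 rose and 1 fell. The median was 0.73 and the adjusted p 1.18e-07, against 0.0224 with an estimated correlation and 0.163 with the estimate and the replicate block. Beside CEBPA, the neutrophil protease gene CTSG (chromosome 14, 25042724 to 25045466) rose from 52.6 ± 9.97 to 127 ± 12.8 FPKM and the repressor gene GFI1 (chromosome 1, 92938602 to 92951657) from 6.06 ± 1.11 to 14.3 ± 3.38 FPKM. LCN2, which encodes a granule protein, fell from 4.83 ± 0.870 to 1.14 ± 0.493 FPKM. Myeloperoxidase, MPO, was 318 ± 81.9 FPKM with the empty vector and 461 ± 131 FPKM under knock-down, with an adjusted p of 0.242 and of 0.0372 with the replicate block. In the monocyte and macrophage list 1 of 21 members rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. With the block 9 rose and 1 fell. The median was 0.36 and the adjusted p 0.00515 (adjusted p = 0.19 with an estimated correlation). SPI1, which encodes the myeloid factor PU.1 (chromosome 11, 47376409 to 47400127), rose from 18.2 ± 0.940 to 30.4 ± 1.63 FPKM, and APOE fell from 4.64 ± 1.77 to 2.01 ± 0.152 FPKM.

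Of 29 stem and early progenitor genes, 8 rose and 0 fell, with the same counts when adjusted over the list alone. With the replicate block 14 rose and 5 fell. Their median was 0.32 and the adjusted p 5.78e-06 (adjusted p = 0.225 with an estimated correlation). PROM1 rose from 4.16 ± 0.283 to 8.88 ± 0.969 FPKM, BAALC from 2.91 ± 0.772 to 7.83 ± 0.751 FPKM, and the transcription factor gene ERG from 3.43 ± 0.469 to 7.58 ± 0.350 FPKM. CD34 was 9.33 ± 1.21 FPKM with the empty vector and 11.2 ± 2.10 FPKM under knock-down (adjusted p 0.542), and the stem cell factor receptor KIT 39.5 ± 1.24 and 41.5 ± 4.80 FPKM (adjusted p 0.741). Of the other RUNX family genes, RUNX1 was 27.2 ± 0.602 and 35.2 ± 2.78 FPKM (adjusted p 0.284), RUNX2 1.84 ± 0.320 and 3.88 ± 0.485 FPKM (adjusted p 0.139, and 0.0438 with the replicate block) and CBFB 54.4 ± 1.32 and 59.5 ± 4.68 FPKM (adjusted p 0.529).

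Genes outside these lists were among the largest changes. TMEM176B (chromosome 7, 150488376 to 150497621), whose locus overlaps TMEM176A, rose from 0.954 ± 1.18 to 7.89 ± 3.29 FPKM. BZRAP1 (chromosome 17, 56378588 to 56406152), which overlaps an antisense gene, rose from 3.95 ± 0.231 to 14.5 ± 4.54 FPKM. CD38, an ectoenzyme of committed progenitors (chromosome 4, 15779888 to 15854866), rose from 4.22 ± 1.40 to 15.5 ± 9.08 FPKM, and CRIM1 (chromosome 2, 36583370 to 36778278) from 4.11 ± 1.80 to 11.6 ± 1.04 FPKM. THAP3, HSPE1 and ALKBH4 also met the naming rule but are listed at 0 in every library of one group, and each overlaps another gene. HSPE1 (chromosome 2, 198364721 to 198368187), which encodes a mitochondrial co-chaperonin and overlaps HSPD1, is listed at 0, 0 and 0 under knock-down.

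Several lists of cell growth moved by smaller amounts. Ribosome biogenesis genes had 2 of 32 members that fell and 0 that rose (10 falling adjusted over the list alone), S phase genes 6 of 40 that fell and 0 that rose (6 adjusted over the list alone), and G2 and mitosis genes 2 of 42 that fell and 0 that rose (0 adjusted over the list alone). These counts rest on whether the pairing of the libraries is used. With the replicate number as a block 28 ribosome biogenesis genes, 30 S phase genes and 30 G2 and mitosis genes fell, and 0, 0 and 1 rose. Their adjusted p values were 1.68e-05, 3.4e-05 and 0.00148, each with an adjusted p = 0.554 with an estimated correlation. UNG, a uracil glycosylase, fell from 69.9 ± 2.90 to 42.7 ± 3.39 FPKM, the nucleolar gene RRS1 from 21.1 ± 2.39 to 14.7 ± 1.38 FPKM, and the mitotic activator gene CDC20 from 43.1 ± 9.01 to 23.0 ± 4.30 FPKM. The histone list had 1 of 54 members that fell and 0 that rose (0 adjusted over the list alone), with a median of −0.19 and an adjusted p of 0.00145 (adjusted p = 0.566 with an estimated correlation). The 79 ribosomal protein genes had 0 members past the limma test in either count and 1 at an unadjusted p under 0.05, and with the block 2 rose. Their median was 0.11, with an adjusted p of 5.51e-05 (adjusted p = 0.554 with an estimated correlation).

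Cholesterol and fatty acid synthesis genes had 7 of 31 members that fell and 0 that rose (8 falling adjusted over the list alone, and 13 with the replicate block), with an adjusted p of 0.00687 (adjusted p = 0.554 with an estimated correlation). LSS, a cyclase of sterol synthesis, fell from 37.1 ± 4.18 to 19.6 ± 1.75 FPKM and the fatty acid desaturase gene FADS2 from 184 ± 2.43 to 121 ± 1.55 FPKM. Lysosome and autophagy genes had 2 of 29 that rose and 2 that fell in both counts, and 8 and 5 with the block (adjusted p 0.0356, and adjusted p = 0.402 with an estimated correlation). ATP6V0D1, a subunit of the proton pump of lysosomes (chromosome 16, 67471917 to 67515089), fell from 38.4 ± 0.740 to 14.5 ± 0.806 FPKM, with an adjusted p of 7.23e-05. The lymphoid list had 3 of 8 that rose and 0 that fell in both counts (adjusted p 0.00981, and adjusted p = 0.211 with an estimated correlation), among them the cytotoxic granule gene NKG7, from 10.7 ± 2.38 to 19.3 ± 5.36 FPKM. The list of targets of transforming growth factor beta had 1 of 16 that fell and 0 that rose in both counts, and 1 and 5 with the block, with a positive median of 0.25 (adjusted p 0.0152, and adjusted p = 0.19 with an estimated correlation), and its member ID1 fell from 8.25 ± 1.53 to 4.01 ± 0.670 FPKM. Of 30 stress response genes 1 rose over all genes, with 0 adjusted over the list alone and 0 that fell, and 4 rose with the block. Of 12 MHC class II genes 0 passed the limma test in either count and 2 lay at an unadjusted p under 0.05, and with the block 2 rose. The adjusted p values of these lists were 0.037 and 0.0395, and for both adjusted p = 0.554 with an estimated correlation.

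The remaining lists did not pass. Glycolysis genes had 3 of 24 that fell and 0 that rose in both counts, and 8 and 1 with the replicate block (adjusted p 0.07). Immediate early genes had 1 of 18 that rose and 0 that fell in both counts, and 2 each with the block (adjusted p 0.07). The 1 that rose without the block was FOSL2 (chromosome 2, 28615779 to 28637516), from 4.82 ± 0.444 to 11.1 ± 1.53 FPKM. The dendritic cell list had 0 of 6 past the limma test over all genes, 3 at an unadjusted p under 0.05, and 1 rising and 1 falling adjusted over the list alone, or 2 and 1 with the block (adjusted p 0.147). In the list of mast cells, basophils and eosinophils 0 of 17 passed in either count, with 1 at an unadjusted p under 0.05, and 1 rose and 3 fell with the block (adjusted p 0.177). NF-kB and inflammatory genes had 1 of 22 that rose and 3 that fell, or 2 and 3 adjusted over the list alone and 4 and 4 with the block (adjusted p 0.177). One of them, the chemokine gene CCL2 (chromosome 17, 32582296 to 32584220), rose from 0.755 ± 0.318 to 5.01 ± 3.16 FPKM. Interferon response genes had 2 of 29 that rose and 2 that fell, or 2 and 3 adjusted over the list alone and 7 and 10 with the block (adjusted p 0.486). For p53 targets 1 of 30 rose and 1 fell in both counts, and 4 and 3 with the block (adjusted p 0.398). For the RUNX family 0 of 5 passed in either count, with 2 at an unadjusted p under 0.05, and 1 rose with the block (adjusted p 0.311). For stromal and endothelial genes 0 of 9 passed over all genes, with 3 at an unadjusted p under 0.05, and 1 rose and 1 fell adjusted over the list alone, or 3 and 1 with the block (adjusted p 0.398). In the interferon, p53 and stromal lists the median and the mean differed in sign. The 13 mitochondrially encoded genes have no values in the files.

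Across all 11769 genes tested, 1316 passed the limma test, of which 462 rose and 854 fell. With the replicate number as a block, 3897 passed, of which 1238 rose and 2659 fell, and all 1316 were among them. With median-of-ratios scaling 610 rose and 650 fell, a share of 48.4% higher calls against 35.1% with FPKM as deposited. With short loci left out and each library rescaled, 282 passed, and leaving out 1 library gave from 486 (without erythroid empty vector replicate 3) to 2089 (without CD34+ empty vector replicate 2).

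**Figure D2:**
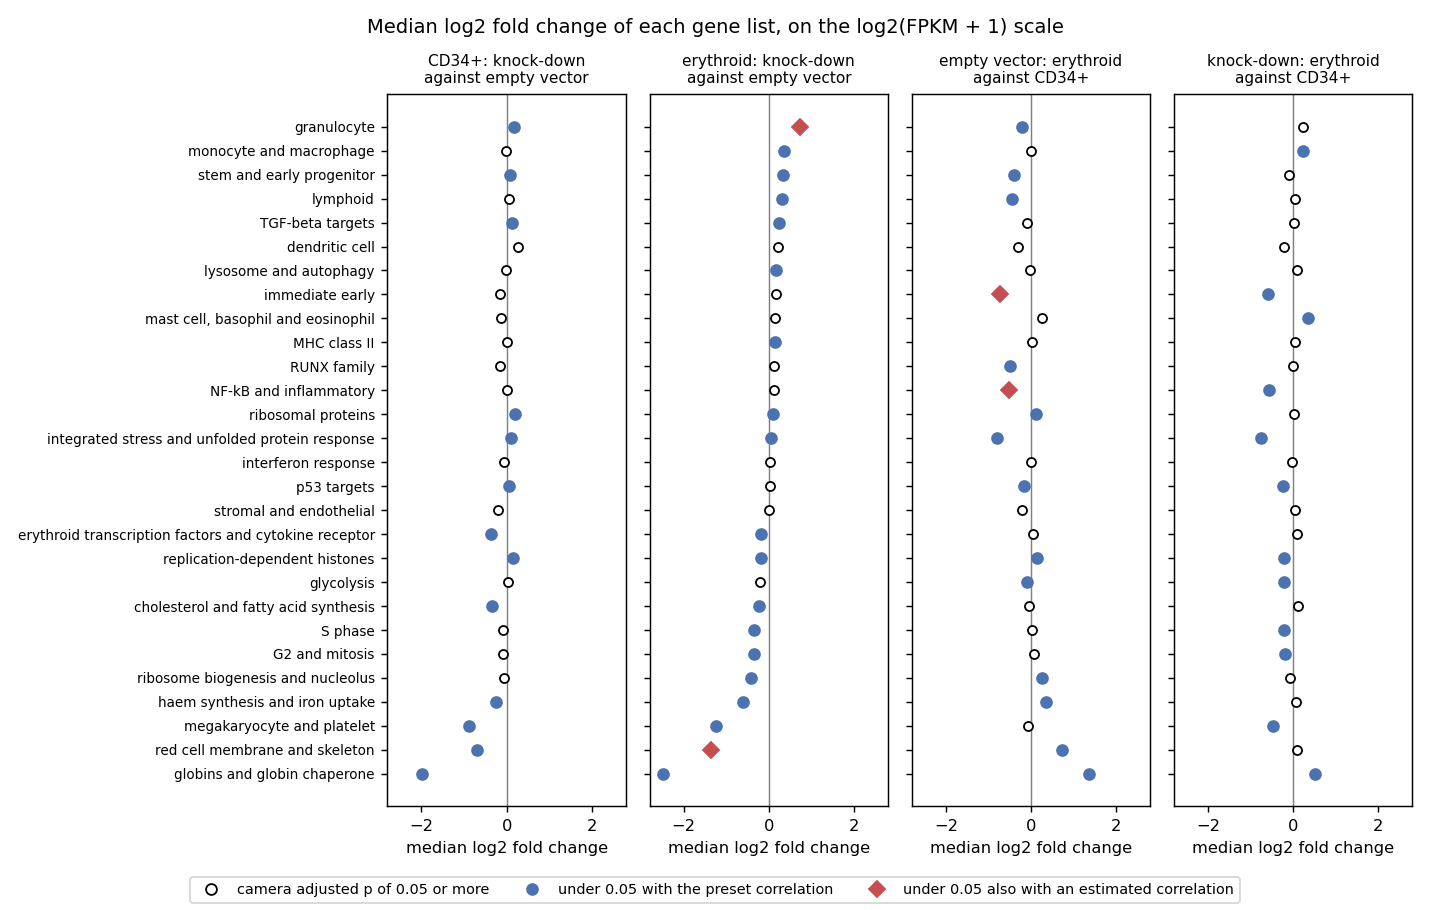
Median log2 fold change (horizontal axis) of each gene list in the 4 comparisons. In erythroid medium under knock-down the globin list has a median of −2.48 and the granulocyte list one of 0.73, and the list medians whose sign changes with another scaling between libraries are at most 0.085 from 0.

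The comparison of knock-down with empty vector in undifferentiated CD34+ cells asks what the construct changed before erythroid medium. Members of the platelet, globin and red cell membrane lists fell here too, 3 of 22, 3 of 10 and 6 of 20 of them. As lists they do not pass with an estimated correlation (adjusted p = 0.26, 0.254 and 0.0749). PPBP fell from 74.8 ± 8.09 to 15.8 ± 5.70 FPKM (SD, n = 3), HBG1 from 64.0 ± 22.2 to 14.0 ± 2.38 FPKM, and RHAG, which encodes a membrane channel of red cells (chromosome 6, 49572890 to 49604587), from 27.8 ± 7.52 to 8.14 ± 2.70 FPKM. KLF1 fell from 41.3 ± 3.32 to 22.7 ± 2.27 FPKM, and CEBPA rose from 55.6 ± 5.88 to 88.9 ± 7.18 FPKM.

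Red cell membrane and skeleton genes had 6 of 20 members that fell and 0 that rose, and 15 fell when adjusted over the list alone and 17 with the replicate block. The list had a median of −0.70 and an adjusted p of 3.6e-14 (adjusted p = 0.0749 with an estimated correlation). Besides RHAG, KEL fell from 3.19 ± 0.314 to 1.28 ± 0.287 FPKM and EPB41 from 42.1 ± 0.645 to 31.8 ± 1.33 FPKM. Globins had 3 of 10 that fell and 0 that rose (9 falling adjusted over the list alone, and 8 with the block), with a median of −1.99 and an adjusted p of 1.79e-08 (adjusted p = 0.254 with an estimated correlation). The delta-globin gene HBD (chromosome 11, 5254059 to 5255858) fell from 569 ± 104 to 245 ± 15.1 FPKM and HBQ1 from 10.6 ± 2.71 to 3.32 ± 0.109 FPKM. HBB was 459 ± 321 FPKM with the empty vector and 120 ± 102 FPKM under knock-down (adjusted p 0.146, and 0.00833 with the replicate block), and HBA1 67.6 ± 75 and 11.2 ± 8.29 FPKM (adjusted p 0.213, and 0.0106 with the block).

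Megakaryocyte and platelet genes had 3 of 22 that fell and 0 that rose, and 11 fell when adjusted over the list alone and 12 with the replicate block, with a median of −0.89 and an adjusted p of 7.59e-10 (adjusted p = 0.26 with an estimated correlation). PF4 fell from 51.7 ± 17.3 to 18.3 ± 4.85 FPKM and CLEC1B from 2.85 ± 1.62 to 0.388 ± 0.193 FPKM. Erythroid transcription factors had 3 of 17 that fell and 0 that rose (9 falling and 1 rising adjusted over the list alone, and 8 falling with the block), with an adjusted p of 7.24e-05 (adjusted p = 0.26 with an estimated correlation). TAL1 fell from 57.1 ± 4.79 to 40.5 ± 1.31 FPKM and GFI1B from 40.8 ± 6.18 to 25.3 ± 2.60 FPKM, while GATA1 was 44.5 ± 6.86 and 31.4 ± 4.59 FPKM (adjusted p 0.124, and 0.0345 with the block). Of 22 haem and iron genes 1 fell and 0 rose (6 falling adjusted over the list alone, and 9 with the block), with an adjusted p of 0.00087 (adjusted p = 0.26 with an estimated correlation). The gene that fell without the block was TFR2, which encodes a sensor of transferrin, from 20.1 ± 0.982 to 13.2 ± 0.519 FPKM.

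Cholesterol and fatty acid genes had 2 of 31 that fell and 0 that rose (12 falling adjusted over the list alone, and 13 with the replicate block), with a median of −0.35 and an adjusted p of 1.02e-11 (adjusted p = 0.26 with an estimated correlation). LSS fell from 35.0 ± 9.30 to 15.8 ± 2.14 FPKM and FADS2 from 226 ± 27.5 to 148 ± 12.2 FPKM. Ribosomal protein genes had a median of 0.20, with 0 of 79 past the limma test in either count and 0 at an unadjusted p under 0.05. Their adjusted p as a list was 6.49e-16 (adjusted p = 0.541 with an estimated correlation). Histone genes had a median of 0.14, with 0 of 54 past the limma test in either count and 0 at an unadjusted p under 0.05. Their adjusted p was 5.84e-09 (adjusted p = 0.645 with an estimated correlation).

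Of the lists that passed, 5 more had positive medians. In the granulocyte list 1 of 20 rose and 0 fell, or 1 and 1 adjusted over the list alone and 2 and 1 with the replicate block, with an adjusted p of 0.0129 (adjusted p = 0.26 with an estimated correlation). Of 30 stress response genes 0 passed the limma test in either count and 1 lay at an unadjusted p under 0.05, with an adjusted p of 0.00223 for the list (adjusted p = 0.559 with an estimated correlation). For 16 targets of transforming growth factor beta both counts and the count at an unadjusted p under 0.05 were 0, and 1 rose with the block, with an adjusted p of 0.0435 (adjusted p = 0.26 with an estimated correlation). Stem and progenitor genes had 0 of 29 past the limma test over all genes, 5 at an unadjusted p under 0.05 and 2 rising adjusted over the list alone. With the block 3 rose and 2 fell. Without it the adjusted p of the list was 0.0296 (adjusted p = 0.674 with an estimated correlation). The p53 targets had 0 of 30 past the limma test over all genes, 4 at an unadjusted p under 0.05 and 2 rising adjusted over the list alone or with the block, with an adjusted p of 0.0473, or 0.058 with the block (adjusted p = 0.717 with an estimated correlation). The positive medians of the stem and p53 lists turned negative when short loci were left out. The other 15 lists did not pass, and in the glycolysis, interferon, monocyte and NF-kB lists the median, the mean and the test differed in sign. In the NF-kB list 1 of 22 fell and 0 rose, or 3 and 1 with the block, and the 1 that fell without it was the prostaglandin synthase gene PTGS2 (chromosome 1, 186640944 to 186649559), from 10.5 ± 0.544 to 4.45 ± 0.878 FPKM.

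The gene that rose most was ADAM9, a membrane protease (chromosome 8, 38854505 to 38962779), from 7.70 ± 0.302 to 19.1 ± 2.31 FPKM, a log2 fold change of 1.20 ± 0.15 (SE) with an adjusted p of 0.00697. GALC, a lysosomal galactosidase (chromosome 14, 88399358 to 88459615), rose from 20.3 ± 2.74 to 35.4 ± 3.96 FPKM and FOSL2 from 7.10 ± 1.19 to 12.8 ± 1.93 FPKM. COPS6, a subunit of the signalosome (chromosome 7, 99686583 to 99689822), fell from 26.2 ± 3.53 to 9.0 ± 0.627 FPKM, OSBP2, a sterol-binding protein gene (chromosome 22, 31277668 to 31303811), from 8.13 ± 2.17 to 1.89 ± 0.691 FPKM, and ATP6V0D1 from 39.3 ± 1.08 to 16.5 ± 2.16 FPKM. CD34 was 16.2 ± 4.29 and 13.9 ± 3.83 FPKM (adjusted p 0.76), KIT 31.7 ± 1.35 and 28.5 ± 3.46 FPKM (adjusted p 0.569), SPI1 33.3 ± 4.69 and 34.2 ± 0.892 FPKM (adjusted p 0.903) and MPO 388 ± 89.1 and 362 ± 93.4 FPKM (adjusted p 0.922). RUNX1 was 40.9 ± 16.6 and 35.2 ± 1.17 FPKM (adjusted p 0.823), RUNX2 4.15 ± 3.16 and 3.15 ± 0.571 FPKM (adjusted p 0.888) and CBFB 53.3 ± 7.29 and 60.0 ± 7.52 FPKM (adjusted p 0.577).

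Over all genes 90 passed the limma test, of which 5 rose and 85 fell. With the replicate block 784 passed, of which 154 rose and 630 fell, and all 90 were among them. Median-of-ratios scaling gave 7 higher and 48 lower genes, a share of 12.7% higher calls against 5.56% with FPKM as deposited, and leaving short loci out gave 31 genes. A fit of only the 2 groups gave 2 genes, with 0 of the 90 among them, though all 90 lay there at an unadjusted p under 0.05 in the same direction. Leaving out 1 library gave from 29 genes (without CD34+ knock-down replicate 2) to 112 (without CD34+ empty vector replicate 2).

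The log2 fold changes under knock-down in the 2 cultures share no library. The calls share the spread per gene, which is pooled over all 12 libraries, and libraries of the 2 cultures with the same number deviate alike. The cultures are therefore not independent, and no overlap expected by chance is given. Of the 85 genes that fell in CD34+ cells 85 were lower in erythroid medium, where 77 passed, and all 5 that rose in CD34+ cells also rose in erythroid medium. With the replicate block 531 of the 630 that fell and 127 of the 154 that rose in CD34+ cells did so in erythroid medium too. Across the 11769 genes, which are not independent replicates, the log2 fold changes of the cultures had a Pearson correlation of 0.502 and a Spearman correlation of 0.52.

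**Figure D3:**
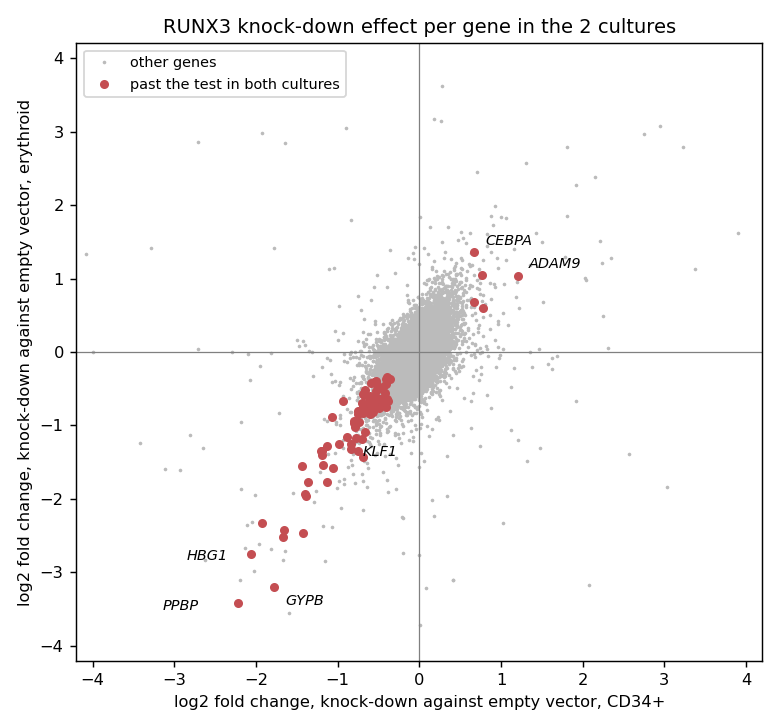
Log2 fold change under knock-down of each gene in CD34+ cells (horizontal axis) and in erythroid medium (vertical axis), with genes past the test in both as large points and 10 genes outside the axes. PPBP lies at −2.22 and −3.42, and CEBPA at 0.67 and 1.36.

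The difference between the knock-down effects of the cultures was tested directly as an interaction. It passed for 2 genes of 11769, 1 in each direction, with 658 genes at an unadjusted p under 0.05 and 2 genes also with the replicate block. Both were chosen for naming after their values were seen. EEF2KMT, a lysine methyltransferase (chromosome 16, 5134301 to 5147821), whose locus overlaps ALG1, is listed at 0 in all 3 erythroid knock-down libraries and at 3.61, 3.18 and 4.53 FPKM in the erythroid empty vector libraries. In CD34+ cells it was at 3.71, 2.59 and 2.75 FPKM with the empty vector and 2.82, 2.15 and 2.37 FPKM under knock-down. The microRNA gene MIR1224 (chromosome 3, 183959193 to 183959277), 85 bases long and inside VWA5B2, is listed at 0 in 9 libraries and at 2326, 6896 and 1991 FPKM in the erythroid knock-down libraries. No member of any fixed list passed over all genes, so the larger changes of KLF1 or PPBP in erythroid medium are not shown to differ from those in CD34+ cells at the level of the gene. At the level of lists, 19 of 28 passed camera with the preset correlation and 0 with an estimated one, where 3 lay at an unadjusted p under 0.05. Red cell membrane genes were lower by a median of −0.54 in erythroid medium beyond the effect in CD34+ cells (adjusted p 5.95e-11, and adjusted p = 0.0787 with an estimated correlation), and granulocyte genes higher by 0.59 (adjusted p 2.95e-06, and adjusted p = 0.0678 with an estimated correlation).

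The comparison of erythroid with CD34+ cells carrying the empty vector shows what 24 h of erythroid medium did without knock-down. Members of the red cell membrane, haem and globin lists rose, 8 of 20, 6 of 22 and 3 of 10 of them, and members of the stress, NF-kB and immediate early lists fell, 13 of 30, 8 of 22 and 11 of 18. With an estimated correlation the NF-kB and immediate early lists pass (adjusted p = 0.0497 and 0.04) and the others do not, as given below. AHSP, the chaperone of alpha-globin (chromosome 16, 31539173 to 31540125), rose from 6.59 ± 4.94 to 43.8 ± 25.5 FPKM (SD, n = 3) and HBA1 from 67.6 ± 75 to 407 ± 193 FPKM, with the reservation that its reads are hard to tell from those of HBA2. KLF1 rose from 41.3 ± 3.32 to 67.8 ± 5.48 FPKM. FOS, an immediate early transcription factor (chromosome 14, 75745481 to 75748937), fell from 35.6 ± 13.6 to 4.11 ± 0.251 FPKM.

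Red cell membrane genes had 8 of 20 that rose and 0 that fell (15 rising adjusted over the list alone, and 14 with the replicate block), with a median of 0.73 and an adjusted p of 6.19e-10 (adjusted p = 0.0557 with an estimated correlation). ADD2, a skeletal adducin, rose from 3.66 ± 0.593 to 9.48 ± 2.58 FPKM. Haem and iron genes had 6 of 22 that rose and 0 that fell (9 rising adjusted over the list alone, and 12 with the block), with an adjusted p of 1.51e-07 (adjusted p = 0.0528 with an estimated correlation). ABCB6 rose from 6.22 ± 0.487 to 12.1 ± 0.715 FPKM and BLVRB from 85.6 ± 16.3 to 189 ± 8.96 FPKM. Globins had 3 of 10 that rose and 0 that fell (9 rising adjusted over the list alone, and 8 with the block), with a median of 1.37 and an adjusted p of 7.84e-07 (adjusted p = 0.131 with an estimated correlation). HBB was 459 ± 321 FPKM in CD34+ cells and 1360 ± 244 FPKM in erythroid medium (adjusted p 0.126, and 0.00721 with the replicate block). Erythroid transcription factors had 2 of 17 that rose and 0 that fell (3 rising adjusted over the list alone, and 5 with the block) without passing as a list (adjusted p 0.0923), and LDB1, which joins GATA1 complexes to distant enhancers, rose from 47.0 ± 2.88 to 69.0 ± 7.25 FPKM. GATA1 was 44.5 ± 6.86 and 47.7 ± 3.56 FPKM (adjusted p 0.675). The pyruvate kinase gene of red cells, PKLR (chromosome 1, 155259084 to 155271225), which overlaps HCN3, rose from 2.08 ± 1.25 to 14.8 ± 7.60 FPKM, and the tubulin gene TUBB2A (chromosome 6, 3153902 to 3157783) from 6.54 ± 3.30 to 25.4 ± 7.37 FPKM.

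Immediate early genes had 11 of 18 that fell and 0 that rose (16 falling adjusted over the list alone), with a median of −0.73 and an adjusted p of 4.78e-16, against 0.04 with an estimated correlation and 0.125 with the estimate and the block. EGR1 (chromosome 5, 137801181 to 137805004) fell from 9.02 ± 6.64 to 0.651 ± 0.113 FPKM and the phosphatase gene DUSP1 (chromosome 5, 172195093 to 172198203) from 16.4 ± 1.77 to 7.73 ± 1.14 FPKM. Of 30 stress response genes 13 fell and 0 rose (17 falling adjusted over the list alone), with a median of −0.80 and an adjusted p of 1.78e-13 (adjusted p = 0.0901 with an estimated correlation). The serine synthesis gene PHGDH (chromosome 1, 120254419 to 120286849) fell from 125 ± 41.1 to 23.8 ± 3.08 FPKM, PSAT1 of the same pathway (chromosome 9, 80911991 to 80945009) from 67.5 ± 39.8 to 9.66 ± 0.580 FPKM, CHAC1 (chromosome 15, 41245669 to 41248717) from 9.15 ± 5.15 to 0.268 ± 0.0283 FPKM, and XBP1, a factor of the unfolded protein response (chromosome 22, 29190548 to 29196560), from 181 ± 13.8 to 89.9 ± 4.75 FPKM. NF-kB and inflammatory genes had 8 of 22 that fell and 0 that rose (12 falling adjusted over the list alone), with an adjusted p of 5.18e-11, against 0.0497 with an estimated correlation and 0.143 with the estimate and the block. The chemokine gene CXCL8 (chromosome 4, 74606223 to 74609433) fell from 57.1 ± 8.27 to 7.30 ± 3.86 FPKM and PTGS2 from 10.5 ± 0.544 to 1.45 ± 0.472 FPKM. CD69, an activation marker (chromosome 12, 9905082 to 9913497), fell from 70.8 ± 23.2 to 7.14 ± 0.559 FPKM.

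Stem and progenitor genes had 4 of 29 that fell and 0 that rose (14 falling and 1 rising adjusted over the list alone, and 16 and 2 with the replicate block), with a median of −0.39 and an adjusted p of 7.79e-07 (adjusted p = 0.174 with an estimated correlation). GATA2 (chromosome 3, 128198265 to 128212030) fell from 116 ± 14.8 to 67.5 ± 10.2 FPKM and PROM1 from 7.25 ± 0.353 to 4.16 ± 0.283 FPKM, while CD34 was 16.2 ± 4.29 and 9.33 ± 1.21 FPKM (adjusted p 0.128, and 0.00865 with the block) and KIT 31.7 ± 1.35 and 39.5 ± 1.24 FPKM (adjusted p 0.135, and 0.0239 with the block). Granulocyte genes had 2 of 20 that fell and 0 that rose (3 falling adjusted over the list alone, and 6 with the block), with an adjusted p of 0.00749 (adjusted p = 0.131 with an estimated correlation), among them CEBPA from 55.6 ± 5.88 to 34.8 ± 6.50 FPKM. SPI1 fell from 33.3 ± 4.69 to 18.2 ± 0.940 FPKM. Of 30 p53 targets 5 fell and 0 rose (7 falling adjusted over the list alone), with an adjusted p of 0.0061 (adjusted p = 0.567 with an estimated correlation), among them the cell cycle inhibitor gene CDKN1A (chromosome 6, 36646456 to 36655116), from 35.5 ± 4.32 to 15.9 ± 4.96 FPKM. Lymphoid genes had a negative median, with 0 of 8 past the limma test over all genes, 4 at an unadjusted p under 0.05 and 4 falling adjusted over the list alone or with the block. Their adjusted p was 0.012 (adjusted p = 0.174 with an estimated correlation). Of 24 glycolysis genes 2 fell and 0 rose, or 5 and 2 adjusted over the list alone or with the block, with an adjusted p of 0.0394 (adjusted p = 0.414 with an estimated correlation). Of the RUNX family 0 of 5 passed the limma test over all genes, 2 lay at an unadjusted p under 0.05 and 1 fell adjusted over the list alone or with the block. The adjusted p of that list was 0.0447, or 0.0891 with the block (adjusted p = 0.399 with an estimated correlation).

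Positive medians were found for genes of ribosomes and chromatin, with 0 members past the limma test in either count. With the replicate block 10 ribosome biogenesis genes rose and 1 fell, and 1 histone gene rose. Of 32 ribosome biogenesis genes 5 lay at an unadjusted p under 0.05, and the list had an adjusted p of 0.000213 (adjusted p = 0.638 with an estimated correlation). Of 54 histone genes 1 lay at an unadjusted p under 0.05, and the list had an adjusted p of 0.00114 (adjusted p = 0.801 with an estimated correlation). Of 79 ribosomal protein genes 0 did, and the list had an adjusted p of 0.0172 (adjusted p = 0.892 with an estimated correlation). Without CD34+ empty vector replicate 2 the medians of the histone and ribosomal protein lists turned negative. The other 13 lists did not pass. The dendritic cell list had an adjusted p of 0.059, or 0.0457 with the block, and the median and the mean or the test differed in sign for interferon, MHC class II, monocyte and megakaryocyte genes.

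Over all genes 410 passed the limma test, of which 127 rose and 283 fell, and with the replicate block 1962 passed, of which 957 rose and 1005 fell, including all 410. Leaving short loci out gave 133 genes and a fit of only the 2 groups 108, of which 102 are among the 410. Leaving out 1 library gave from 99 (without erythroid empty vector replicate 1) to 524 (without CD34+ empty vector replicate 1). SCO2, SLC7A6OS, ALKBH4 and a readthrough of CCZ1P met the naming rule but are listed at 0 in every CD34+ empty vector library and overlap other genes.

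The same comparison under knock-down shows what erythroid medium did to cells carrying the knock-down construct. Members of the stress, NF-kB and immediate early lists fell again, 12 of 30, 5 of 22 and 5 of 18 of them. As lists they do not pass with an estimated correlation (adjusted p = 0.111, 0.0523 and 0.0523). CXCL8 fell from 58.0 ± 7.45 to 5.75 ± 1.90 FPKM (SD, n = 3), CD69 from 49.4 ± 7.44 to 7.36 ± 0.533 FPKM, and FOS from 21 ± 4.33 to 5.95 ± 0.306 FPKM. KLF1 was 22.7 ± 2.27 FPKM in CD34+ cells and 26.5 ± 2.76 FPKM in erythroid medium (adjusted p 0.403).

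Stress response genes had 12 of 30 that fell and 0 that rose (16 falling adjusted over the list alone), with a median of −0.76 and an adjusted p of 5.99e-15 (adjusted p = 0.111 with an estimated correlation). The asparagine synthetase gene ASNS (chromosome 7, 97481429 to 97501854), which overlaps a readthrough, fell from 78.8 ± 37.2 to 8.31 ± 0.377 FPKM, PSAT1 from 65.1 ± 33.4 to 7.45 ± 1.15 FPKM and SLC3A2, which encodes the heavy chain of amino acid transporters, from 114 ± 28.9 to 48.2 ± 2.33 FPKM. Immediate early genes had 5 of 18 that fell and 0 that rose (16 falling adjusted over the list alone, and 11 with the replicate block), and NF-kB genes 5 of 22 that fell and 0 that rose (13 falling adjusted over the list alone or with the block), with adjusted p values of 4.54e-14 and 8.05e-11 (for both adjusted p = 0.0523 with an estimated correlation). ATF3, a stress-induced factor, fell from 4.45 ± 1.32 to 1.24 ± 0.311 FPKM. Of 30 p53 targets 4 fell and 0 rose (6 falling adjusted over the list alone, and 9 with the block), with an adjusted p of 2.03e-05 (adjusted p = 0.54 with an estimated correlation), and CDKN1A fell from 36.7 ± 5.91 to 13.9 ± 2.63 FPKM. Of 24 glycolysis genes 4 fell and 0 rose (6 falling adjusted over the list alone, and 7 with the block), with an adjusted p of 4.03e-05 (adjusted p = 0.191 with an estimated correlation), and ENO2 fell from 8.03 ± 0.0487 to 4.14 ± 0.486 FPKM.

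Globins had 0 of 10 that rose and 1 that fell, or 4 and 1 when adjusted over the list alone or with the replicate block, with a median of 0.51 and an adjusted p of 0.00508 (adjusted p = 0.546 with an estimated correlation). The member that fell was the embryonic gene HBE1, from 9.73 ± 1.68 to 2.02 ± 0.509 FPKM. HBB was 120 ± 102 and 367 ± 141 FPKM (adjusted p 0.141, and 0.00897 with the block) and HBA1 11.2 ± 8.29 and 62.3 ± 26.1 FPKM (adjusted p 0.115, and 0.00574 with the block). Of 20 red cell membrane genes 0 rose and 1 fell, or 1 and 2 adjusted over the list alone and 5 and 2 with the block, with an adjusted p of 0.412 for the list. Of 22 haem genes 0 passed the limma test over all genes, 6 lay at an unadjusted p under 0.05 and 2 rose adjusted over the list alone. With the block 4 rose and 1 fell. Without it the adjusted p of the list was 0.109. Of 17 erythroid transcription factors 0 passed in either count and 3 lay at an unadjusted p under 0.05, while 2 rose and 1 fell with the block. Without it the adjusted p of the list was 0.247. GATA1 was 31.4 ± 4.59 and 28.3 ± 2.10 FPKM (adjusted p 0.721), CEBPA 88.9 ± 7.18 and 89.7 ± 1.92 FPKM (adjusted p 0.989), SPI1 34.2 ± 0.892 and 30.4 ± 1.63 FPKM (adjusted p 0.506) and MPO 362 ± 93.4 and 461 ± 131 FPKM (adjusted p 0.651). Megakaryocyte genes had 0 of 22 past the limma test over all genes, 8 at an unadjusted p under 0.05 and 2 falling adjusted over the list alone. With the block 8 fell. The median was −0.47, and without the block the adjusted p was 0.000512 (adjusted p = 0.6 with an estimated correlation).

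PTGDS, a prostaglandin synthase (chromosome 9, 139871956 to 139876194), rose from 0.502 ± 0.174 to 5.77 ± 1.80 FPKM, ARRDC3 (chromosome 5, 90664449 to 90679190) from 7.64 ± 1.77 to 23.0 ± 1.49 FPKM, LMO4 (chromosome 1, 87794151 to 87814607) from 16.4 ± 2.27 to 39.2 ± 9.17 FPKM, and CNR2, which encodes a cannabinoid receptor (chromosome 1, 24200460 to 24239817), from 2.14 ± 0.0875 to 5.63 ± 0.251 FPKM. The leukotriene synthase gene LTC4S (chromosome 5, 179220986 to 179223513) rose from 11 ± 0.555 to 21.6 ± 4.68 FPKM. KIT rose from 28.5 ± 3.46 to 41.5 ± 4.80 FPKM and FLT3, another receptor of early progenitors, from 5.56 ± 0.488 to 8.72 ± 0.309 FPKM, while CD34 was 13.9 ± 3.83 and 11.2 ± 2.10 FPKM (adjusted p 0.692). MYC (chromosome 8, 128747680 to 128755197) fell from 85.2 ± 3.34 to 59.9 ± 6.56 FPKM. Histone genes had a negative median with 0 of 54 past the limma test in either count and 5 at an unadjusted p under 0.05, and an adjusted p of 3.53e-08 (adjusted p = 0.637 with an estimated correlation). S phase genes had 1 of 40 that fell and 0 that rose in both counts, and 9 falling with the replicate block, with an adjusted p of 4.03e-05 (adjusted p = 0.656 with an estimated correlation). G2 and mitosis genes had a negative median with 0 of 42 past the limma test in either count and 4 at an unadjusted p under 0.05, 9 falling with the block, and an adjusted p of 0.00047 (adjusted p = 0.741 with an estimated correlation). Monocyte genes had 1 of 21 that rose and 0 that fell, or 4 and 1 adjusted over the list alone and 2 and 0 with the block, with an adjusted p of 0.0138 (adjusted p = 0.312 with an estimated correlation). Mast cell, basophil and eosinophil genes had a positive median with 0 of 17 past the limma test over all genes, 4 at an unadjusted p under 0.05 and 1 rising adjusted over the list alone. With the block 6 rose and 1 fell, and without it the adjusted p of the list was 0.0271 (adjusted p = 0.6 with an estimated correlation).

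The other 16 lists did not pass. Of these, granulocyte, lysosome and ribosome biogenesis genes had adjusted p values of 0.0745, 0.0796 and 0.18, and of 0.00677, 0.0267 and 0.0474 with the block. The median, the mean or the test differed in sign for the lists of interferon, lymphoid, RUNX family, stromal and transforming growth factor beta genes. Over all genes 204 passed the limma test, of which 60 rose and 144 fell, and with the replicate block 1373 passed, of which 607 rose and 766 fell, including all 204. Leaving short loci out gave 73 genes and a fit of only the 2 groups 53, of which 42 are among the 204. Leaving out 1 library gave from 22 (without CD34+ knock-down replicate 2) to 343 (without CD34+ empty vector replicate 2). Of the genes that changed in erythroid medium, 22 rose and 90 fell both with the empty vector and under knock-down, and 219 and 407 with the block. These calls share the spread per gene too. Of the 60 that rose and the 144 that fell under knock-down, 57 and 139 had the same sign with the empty vector. Across genes the effects of the medium had a Pearson correlation of 0.448 and a Spearman correlation of 0.405.

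The authors' deposited tables of the 4 comparisons were set beside these calls. At an adjusted p of 0.05 the authors' deposited table lists 452 transcripts higher and 670 lower under knock-down in erythroid medium, and 17 higher and 48 lower in CD34+ cells. For erythroid against CD34+ cells the authors' deposited tables list 81 higher and 261 lower with the empty vector, and 152 higher and 239 lower under knock-down. Of these transcripts past the threshold in the authors' deposited tables whose genes were tested here, 970 of 979, 55 of 55, 249 of 251 and 306 of 307 had the same sign here, in the order erythroid knock-down, CD34+ knock-down, medium with the empty vector and medium under knock-down. Of the genes that passed here and have an adjusted p in the authors' deposited tables, 516 of 763, 27 of 58, 132 of 271 and 98 of 135 also passed there. KLF1 in erythroid medium has a log2 fold change of −1.26 in the authors' deposited table and PPBP one of −2.82. RUNX3 itself has a mean normalized count of 0.145 for its best covered transcript in the authors' deposited table for erythroid medium, with no adjusted p.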

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

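Of the tests in this part, those of overlapping and very short loci, of genes with low counts in the authors' deposited tables and of the reads those tables hold were chosen after the result was seen. Each result here drew attention because the effect of the knock-down differed between the erythroid and the CD34+ culture in a test of that difference.

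At the level of genes, EEF2KMT had a difference of −2.03 and MIR1224 one of 11.63 on the log2 scale. The real grouping gave these 2 genes, and 47 of 100 splits drawn within the cultures from 200, the real one included, gave at least as many, so chance is not excluded. The highest other split gave 932 genes, which points to a structure of the samples. That split does not part all 6 numbered pairs of libraries and keeps the real groups of neither culture. Of the 15 other splits drawn that part all 6 pairs the highest gave 3 genes and 4 gave at least 2. Of the 84 that part fewer pairs 42 gave at least 2. In the same order, splits that keep the real erythroid groups did so in 2 of 2 and 5 of 5. Those that keep the real CD34+ groups did so in 0 of 3 and 0 of 5, and those that keep neither in 2 of 10 and 37 of 74. Splits that keep the erythroid groups keep the contrast in which both genes differ, and mixed groups can carry part of the knock-down effect. The count of 47 is therefore not one expected by chance alone.

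At the level of lists, 19 passed camera with the preset correlation and 0 with an estimated one. Effects in erythroid medium were lower than in CD34+ cells for histones (adjusted p 6.71e-17), red cell membrane genes (5.95e-11), ribosome biogenesis (2.03e-07), haem and iron genes (2.95e-06), S phase (9.55e-05), G2 and mitosis (0.000428), megakaryocyte genes (0.00108) and globins (0.00305). They were also lower for ribosomal proteins (0.0308, and 0.0907 with the block) and glycolysis (0.0446), where the sign of the median changed when short loci were left out. Effects were higher in erythroid medium for granulocyte genes (adjusted p 2.95e-06), stem and progenitor genes (1.57e-05), cholesterol and fatty acid genes (0.00305), lymphoid genes (0.0468) and mast cell, basophil and eosinophil genes (0.0468). Immediate early, lysosome, monocyte and RUNX family genes were higher too, each with an adjusted p of 0.0093. The RUNX family list holds RUNX3, the gene knocked down. Without CD34+ empty vector replicate 2 the log2 fold changes of RUNX1 and RUNX2 in CD34+ cells moved from −0.14 and −0.15 to 0.16 and 0.31.

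EEF2KMT and MIR1224 belong to a pattern of 27 genes listed at 0 in every library of one group and at 1 FPKM or more in every library of another. If transcripts were truly lost or gained, the authors' deposited tables, made from separately counted reads, should show it, yet the median log2 fold change there in the direction seen here was 0.13 (quartiles 0.05 and 0.44) over the 17 values, from 13 genes, with a mean normalized count of at least 20, and 0.205 with 1 mean value per gene, which argues against that explanation for these 13 genes as a set, though HSPE1 reached −1.16. Shared reads may be missing from the authors' deposited tables and their values may be shrunk, yet 15 of the 17 values hold at least 10% of the usual reads, and of 69 values of other genes that changed here by at least 1.5, 64 reached 1 there. A locus that overlaps another gene or is under 300 bases was found in 92.6% of these genes, 25 of 27, passed or not. Of the genes outside the pattern that passed in a comparison, 30.0%, 481 of 1606, had one (Fisher's exact test, one-sided, p = 2.23e-11). Division of reads between overlapping or very short loci by Cufflinks may therefore account for many of these zeros. A real change stays open for HSPE1 and for the other 14 genes, among them GNG8, EEF2KMT, MIR1224 and HBZ. HBZ is at 2.18 in the authors' deposited table with no overlapping locus. Of the values of these 14 genes 33.3% have a mean normalized count of at least 10. EEF2KMT and MIR1224 have counts of 4.37 and 0.324 for knock-down in erythroid medium, too few to decide.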

How the results depend on the processing

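No alternative was added to those fixed beforehand. The log2 fold changes of RUNX3 under knock-down in both cultures, and of each named gene that passed, kept their sign under each of them. Of 6390 values of named genes under the alternatives, 5535 stayed on their side of the threshold, and 792 lost and 63 gained the threshold. In 86 of them the sign of the rounded value differed, each for a gene past the threshold neither as reported nor in that setting, with a reported log2 fold change of at most 0.27, among them RUNX1, RUNX2 and SPI1 in CD34+ cells under knock-down. Of 2660 list values, 2388 stayed, 204 lost and 63 gained the threshold, and 5 changed the direction of the test. The sign of the list median differed in 151 of them, 13 of these for lists that passed as reported, with reported medians of at most 0.206. List medians that changed sign with the scaling in the 4 comparisons were at most 0.085 from 0. In the order of the report the replicate block gave 3897, 784, 1962 and 1373 genes in place of 1316, 90, 410 and 204. With median-of-ratios scaling added, the block gave 3590, 669, 2002 and 1415. Apart from the values printed with it in the report, the block changed no call of a list test or named gene there and moved no count of genes printed there per comparison, per list or shared by comparisons by more than 1.5 times. Counts of lists that are not printed there also moved. The counts set beside the authors' deposited tables were made without it. Leaving short loci out with rescaling gave 282, 31, 133 and 73 genes, and 1 in place of 2 for the interaction. In CD34+ cells median-of-ratios scaling gave 55, the row with the highest mean 50 and a fit of only the 2 groups 2 genes. That fit gave 108 and 53 genes for the medium with the empty vector and under knock-down, and 1534 in place of 1316 for knock-down in erythroid medium. Of the genes that passed over all libraries it kept 0 of 90, 102 of 410, 42 of 204 and 1069 of 1316, in the same order, and each of them lay at an unadjusted p under 0.05 in it. The interaction gave 6 genes with no filter and 1 with the highest row. The causes were not tested.

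RUNX3 in erythroid medium was at −0.44 with only the 2 groups, where it passed (adjusted p 0.0267, over alternatives 0.0147 to 0.418). In CD34+ cells it was at −0.98 with no filter, −1.18 with short loci left out and −0.98 with only the 2 groups, where it no longer passed (adjusted p 0.0659, 0.122 and 0.25, over alternatives 0.0134 to 0.25). Leaving out each library, its log2 fold change ranged from −0.49 to −0.41 in erythroid medium, where it passed without CD34+ empty vector replicate 2 (adjusted p 0.0147), and from −1.15 to −0.77 in CD34+ cells. There it no longer passed without CD34+ empty vector replicate 1 (0.0529), CD34+ knock-down replicate 1 (0.0681), 2 (0.126) or 3 (0.114) or erythroid empty vector replicate 3 (0.0564).

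Leaving out a library leaves 2 in its group, with the spread pooled over all groups. Knock-down in erythroid medium then gave 486 (without erythroid empty vector 3) to 2089 genes (without CD34+ empty vector 2), with 517 without erythroid empty vector 1 and 619, 564 and 713 without erythroid knock-down 1, 2 and 3. Knock-down in CD34+ cells gave 29 (without CD34+ knock-down 2) to 112 (without CD34+ empty vector 2), with 58 and 32 without CD34+ empty vector 1 and 3, 39 and 30 without CD34+ knock-down 1 and 3, 39 without erythroid empty vector 3, and 54 and 56 without erythroid knock-down 2 and 3. The medium with the empty vector gave 99 (without erythroid empty vector 1) to 524 (without CD34+ empty vector 1), with 157 and 233 without CD34+ empty vector 2 and 3 and 166 and 104 without erythroid empty vector 2 and 3. Under knock-down it gave 22 (without CD34+ knock-down 2) to 343 (without CD34+ empty vector 2), with 56 without CD34+ knock-down 3, 118 without erythroid empty vector 3 and 23 without erythroid knock-down 2 or 3. The interaction gave 2 to 5 genes, the latter without CD34+ knock-down 3.

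The list results that changed direction had small medians. With the empty vector, leaving out a library moved the median of histones between −0.007 and 0.254 and of ribosomal proteins between −0.006 and 0.209, both lowest without CD34+ empty vector 2. Under knock-down that of ribosomal proteins ranged from −0.07 (without CD34+ knock-down 1) to 0.081. In the interaction it ranged from −0.202 to 0.021 (without CD34+ empty vector 2), and was −0.028 without erythroid knock-down 1, where only its test changed direction. Depth may limit what FPKM can show for low genes such as RUNX3, whose values lay between 2.12 and 7.98, which was not tested.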

Other observations

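Of the tests in this part, the one of words picked from other genes was chosen after the results were seen, and the counting of transcripts per gene in the last of them was corrected after a first run. The real grouping of the 6 libraries gave 1316 genes for knock-down in erythroid medium and the highest of the other 9 splits 2, and in CD34+ cells 90 against 5. For the medium it gave 410 against 4 with the empty vector and 204 against 3 under knock-down. In each comparison just 1 of the 10 splits, the real one, reached its count, and 10 splits are too few for a share under 0.05. The other splits mix the 2 groups compared, so a real effect adds to their spread. Their low counts are therefore not those expected by chance. Among the other splits that also part all 3 numbered pairs the highest counts were 1, 1, 0 and 0 genes.

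Besides blood lineage genes, the 77 genes that fell under knock-down in both cultures hold many genes of no fixed list. YWHAE, which encodes a 14-3-3 protein, had log2 fold changes of −1.36 in CD34+ cells and −1.77 in erythroid medium. The translation factor gene EIF4G2 had −1.20 and −1.34, the mitochondrial hydratase gene ECHS1 −1.18 and −1.53, the lamin gene LMNA −0.76 and −1.35, and the kinase gene AKT1 −0.60 and −0.83. These genes were chosen after their values were seen.

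Of these 77 genes, 16, or 20.8% (95% exact interval 12.4% to 31.5%, 0.595 expected from the share of such genes tested), belong to the 5 erythroid and megakaryocyte lists. These short lists of 91 tested genes do not show whether the other genes belong to the same lineages. An interfering RNA can also lower transcripts that match its seed in the 3' untranslated region, and among 16100 words of 7 bases, searched in 10482 of 10743 coding genes (97.6%), CCGCTGA was the one most linked to lower values in CD34+ cells, at a z of −7.47 against a lowest of −5.1 in 100 shuffles of the genes, and again in erythroid medium, at −6.27, while its z was −1.44 and −2.27 for the effect of the medium with the empty vector and under knock-down. This word and the overlapping TCCGCTG occur in 4 of 5 RUNX3 transcripts, with the same bases around them. CTTCCCC, which stayed within the shuffles at a z of −4.45, occurs in 5 of 5. A match of the construct, whose sequence was not used here, to unintended transcripts may account for part of the pattern. The word follows T, as in RUNX3, in 38 genes, with median log2 fold changes of −0.163 in CD34+ cells and −0.103 in erythroid medium. The medians were −0.186 and −0.19 in the 188 genes where it does not, so the longer match went with no larger fall. Picked in each of 10 parts of the genes from the other parts, the word was the same each time and occurs in 16 of the 59 genes outside the lists that could be searched, 27.1% (95% exact interval 16.4% to 40.3%), against 1.11% of 90 tested members of the lists (0.0281% to 6.04%) and 2.16% of all genes searched, which argues against a fall of red cell and platelet genes as the whole pattern where the list members stand for their lineages. Of the 16 members of the 5 lists that fell 0.0% carry this word, TCCGCTG or CCGCTGT, the 3 words beyond every shuffle in CD34+ cells (95% exact upper limit 20.6%), which argues against such a match as the direct cause of the fall of globin, membrane and platelet genes, and for these an effect of RUNX3, or an indirect effect of other transcripts that fell, stays open and was not tested.

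In the authors' deposited tables many well expressed genes have almost no reads. Of 5678 genes with a mean of at least 10 FPKM here, 3537 had under 10% of the usual reads per FPKM and kilobase in the authors' deposited tables, among them SPI1 and CEBPA at 0% and RUNX1 at 5.25%, while GATA1 stood at 97.1% and KLF1 at 121%. The share was 90.7% for genes with several RefSeq transcripts, 3460 of 3815, and 4.13% for genes with 1, 77 of 1863, and it was 83.4% with 2 transcripts and 97.4% with 6 or more. Among genes with 1 transcript it was 9.78% where the locus overlaps another gene, 54 of 552, and 1.75% where it does not, 23 of 1311. Reads that match several transcripts or genes may therefore have been left out of the authors' counts, and 432, 33, 119 and 64 of the genes that passed here in the 4 comparisons, in the order of the report, lie among those 3537.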
